A study of Mus musculus with 7 samples.

How the data were processed

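RNA was measured in 7 libraries of HopX-positive cells sorted from mouse brain at 3 stages, E15 (n = 2), P3 (n = 2) and adult (n = 3). Per the labels' protocols, total RNA was extracted with a column kit (RNeasy mini) and its quality was checked on a Bioanalyser. Per the submitters' processing notes, bcl2fastq, Bowtie and the mouse build mm9 were used, with no versions given. The program that turned alignments into expression values and its gene annotation are not given in the sources used here. The deposited table gives TPM values made by the authors, with 1 column per library and 24978 rows of genes. The values of each library summed to between 998450 and 999193, as TPM does, and they were used as deposited. TPM keeps no depth, so no counts could be recovered, no count model was run and no floor was set. An exact 0 can be a failed estimate, so such a gene is said only to be listed at 0 and no fold is given against a group at 0.

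Samples were grouped by the stage in their labels, and replicate numbers were taken from the same labels. Values were transformed to log2(TPM + 1). Genes with at least 1 TPM in at least 2 libraries were tested (15931 genes), and 142 rows were at 0 in every library. All 7 libraries entered a single fit with stage as the only term in limma 3.58.1 (R 4.3.3), with lmFit and eBayes with a mean-variance trend. The fit had 4 residual degrees of freedom and a prior of 4.27. The 3 comparisons between stages and the moderated F test used a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. A gene was counted as having a shared level where the 95% confidence interval of every pairwise log2 difference lay within -1 to 1. The overlap of the steps from E15 to P3 and from P3 to the adult was set beside 50 simulations with no effect and beside independent lists (the product of both counts over the genes tested).

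The 42 gene lists were written before the data were examined, as were the tests, the rule for named genes and the alternatives other than those named below as added. Lists with at least 5 tested members were tested with camera in limma (preset correlation 0.01, Benjamini-Hochberg over lists within a comparison), and again with an estimated correlation and with fry. No list call held with an estimated correlation. camera asks whether members changed more than other genes, and fry asks whether they changed at all, so passing fry does not uphold a camera call. Some lists passed fry, such as astrocyte markers from E15 to P3 and ribosomal protein genes from P3 to the adult (fry in limma, Benjamini-Hochberg adjusted p = 0.003177 and 0.004491). Others did not, such as immature neuron genes from E15 to P3 and mature oligodendrocyte markers from P3 to the adult (fry in limma, Benjamini-Hochberg adjusted p = 0.06291 and 0.1788). Counts of changed members are given over all genes and adjusted over the list alone. The named genes were Hopx, the 10 genes with the largest increase and the 10 with the largest decrease in each comparison among genes past the threshold whose stages did not overlap, and up to 4 members of each list with the largest change past the threshold. Where no member passed, up to 2 members with the highest mean were named. Some members that the rule takes are not reported here. Symbols starting with Gm and a digit, LOC, Mir, Snor or Rnu, or ending in Rik, were left out of the largest changes. Genes named outside this rule were chosen after their values were seen, which holds for Cst3 and Mog, for Gfap in the comparison of the adult with P3, for the only members of a list to change one way (such as Ncam1, Prox1 and Pea15a), for levels given per library, and for the examples of genes that changed in both steps.

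In the table, 978 rows shared all values with another row (227 of them tested), and such genes are uncertain. A further 272 rows shared 135 symbols and were tested as listed. The test was checked on simulated data with 50 genes changed at each size. These genes were drawn only from those with a mean log2(TPM + 1) above 2, and the noise was normal. Far fewer genes were changed than were called in the data. The shares recovered therefore need not hold for genes with lower values or for the reported counts. With a log2 change of 2 it recovered 72% of changed genes from E15 to P3, 88% from P3 to the adult and 78% from E15 to the adult, and with a log2 change of 1 it recovered 22%, 20% and 22%.

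The alternatives were other pseudocounts (0.1 and 5), no filter, a stricter filter (mean of at least 5 TPM), median-of-ratios scaling, quantile normalization, limma without the trend, with robust estimation or with array weights, a replicate block, fits on 2 stages alone, a 2-fold minimum, summing rows of a symbol and leaving out each library in turn. Where this left a stage with 1 library, that sample was assumed to vary like the other groups. Testing identical rows once, leaving out the 10 most abundant genes, and leaving out Adult replicates 1 and 3 together were added after the data were seen. A planned count-based alternative was not run because the table holds TPM. Genome coordinates were not used here.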

Results

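RNA-seq was used to measure transcript levels in HopX-positive cells that had been isolated from the brains of C57BL/6 mice by fluorescence-activated cell sorting. Hopx encodes an atypical homeodomain protein found in radial glia, in quiescent neural stem cells and in astrocytes, and the labels describe the sorted cells as neural progenitor cells. The 7 libraries came from 3 stages, which were embryonic day 15 (E15, n = 2), postnatal day 3 (P3, n = 2, replicates 1 and 3) and the adult (n = 3). The labels do not say from which brain region the cells of each stage came. A difference in region therefore cannot be told apart from a change with stage. Each value was a TPM, a share of the transcripts scaled to a fixed total, and the values of a library summed to between 998450 and 999193. TPM keeps no record of the number of reads, so the depth of each library is unknown and no counting interval can be given. The table held 24978 genes, of which 15931 reached at least 1 TPM in at least 2 libraries and were tested. Between 13483 and 14445 genes reached 1 TPM in each library. Genes at 0 made up 19% and 20.05% of the E15 libraries, 21.21% and 19.62% at P3, and 31.43%, 28.39% and 26.49% in the adult. A lower depth of the adult libraries therefore cannot be excluded for genes listed at 0 there. Nothing in the labels says that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. Fold changes are on the log2(TPM + 1) scale and understate the change of genes with low values.

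Hopx was found in every library and was higher at each later stage. It was at 62.9 and 60.5 TPM in the E15 libraries, 171 and 112 TPM in the P3 libraries, and 220, 249 and 230 TPM in the adult libraries. Because the cells had been sorted on HopX, these levels also depend on the gate, and how HopX was detected is not given in the sources used here. Hopx rose by a log2 change of 1.15 from E15 to P3 (SE 0.21, limma, Benjamini-Hochberg adjusted p = 0.0177), by 0.74 from P3 to the adult (SE 0.20, adjusted p = 0.0282) and by 1.90 from E15 to the adult (SE 0.20, adjusted p = 0.0002). The call from E15 to P3 was lost without E15 replicate 1, E15 replicate 2 or P3 replicate 1 (limma, Benjamini-Hochberg adjusted p = 0.123, 0.157 and 0.0949). The call from P3 to the adult was lost without E15 replicate 1 or 2, P3 replicate 3, or Adult replicate 2 or 3 (limma, Benjamini-Hochberg adjusted p = 0.0651, 0.0651, 0.159, 0.0696 and 0.0571). Both calls were also lost with limma without the trend (limma, Benjamini-Hochberg adjusted p = 0.0692 and 0.0865), in fits on the 2 compared stages alone (0.0765 and 0.0621) and with Adult replicates 1 and 3 left out together (0.0761 and 0.121). The call from P3 to the adult was also lost with no filter (0.0629) and with the replicate block (0.0693). The log2 change from P3 to the adult was 0.44 without P3 replicate 3 and 1.05 without P3 replicate 1.

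Each library correlated more closely with the libraries of its own stage than with those of the other stages, and the libraries of E15 and the adult correlated least. Spearman correlations across genes, which are not independent replicates, were 0.958 within E15, 0.950 within P3 and 0.916 to 0.921 within the adult. They were 0.848 to 0.921 between E15 and P3, 0.828 to 0.870 between P3 and the adult, and 0.743 to 0.765 between E15 and the adult. The first principal component held 61.9% of the variance and placed P3 between E15 and the adult, and the second component held 13.9%. A few transcripts took a larger share of the adult libraries. The 10 most abundant genes made up 6.50% and 6.44% of the TPM in the E15 libraries, 10.3% and 8.02% at P3, and 15.04%, 15.2% and 16.5% in the adult. Cst3, which encodes the secreted protease inhibitor cystatin C, was at 854 and 897 TPM at E15, 13200 and 7278 TPM at P3, and 44931, 44589 and 42769 TPM in the adult. The share of TPM from mitochondrially encoded genes was 2.11% and 2.61% at E15, 2.48% and 2.39% at P3, and 5.18%, 4.86% and 6.00% in the adult.

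**Figure D1:**
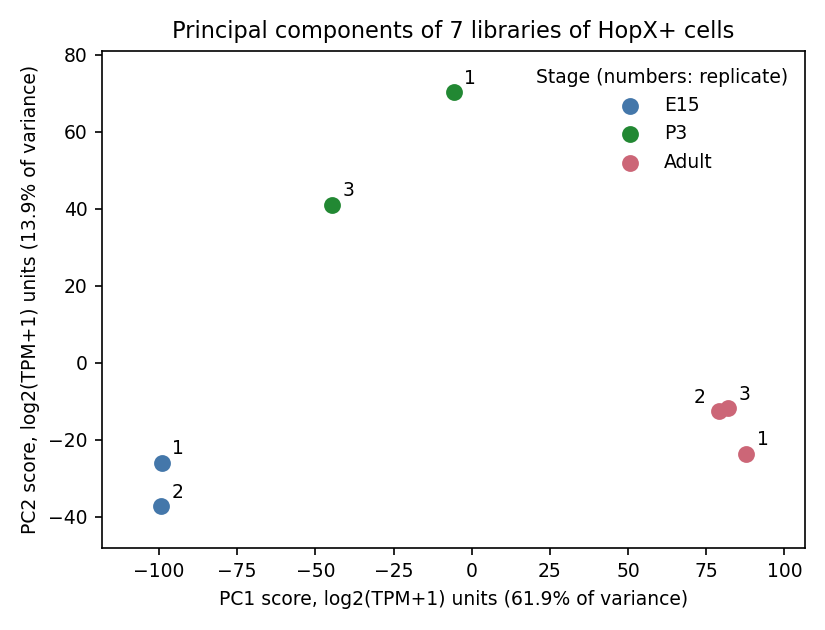
Principal components of log2(TPM + 1) over the tested genes, with 1 point per library, the first component (61.9% of the variance) on the horizontal axis and the second (13.9%) on the vertical axis. The E15 libraries lie at -99.1 and -99.4 on the first component, the P3 libraries at -5.78 and -44.6, and the adult libraries between 79.1 and 87.8.

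The comparison of P3 with E15 asks how HopX-positive cells differ between mid-neurogenesis and the first postnatal days. Astrocyte genes rose. Aqp4, the water channel of astrocyte endfeet, rose from 2.03 ± 1.05 to 215 ± 84.0 TPM (SD, n = 2 per stage), a log2 change of 6.14 (SE 0.32, limma, Benjamini-Hochberg adjusted p = 0.000105). Gfap, the intermediate filament of astrocytes and of adult neural stem cells, rose from 3.47 ± 3.86 to 261 ± 141 TPM, a log2 change of 6.10 (SE 0.61, limma, Benjamini-Hochberg adjusted p = 0.00095). Of 22 astrocyte markers tested, 21 rose and none fell, or 22 and none when adjusted over the list alone. Agt (log2 5.81) and the folate enzyme gene Aldh1l1 (4.61) were among them. The median of the list was 3.23 (camera in limma, Benjamini-Hochberg adjusted p = 4.50e-31, and adjusted p = 0.193 with an estimated correlation). Of 24 genes of adult quiescent stem cells, 21 rose and none fell, or 23 and none when adjusted over the list alone. This list shares Gfap, Aldoc, Ntsr2, Fgfr3 and Gja1 with the astrocyte list, so their results are not independent. Sparcl1, a secreted matricellular protein, had the largest increase among the named genes (log2 7.69, SE 0.31, limma, Benjamini-Hochberg adjusted p = 4.87e-05), and Apoe (4.52) and Ntsr2 (4.31) rose with it. The median of this list was 2.09 (camera in limma, Benjamini-Hochberg adjusted p = 1.40e-30, and adjusted p = 0.193 with an estimated correlation), and 13 members rose without E15 replicate 2. Between the P3 libraries, the median log2 difference of replicate 3 minus replicate 1 was -0.74 for the astrocyte list and -0.74 for the quiescent stem cell list.

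Genes of radial glia moved both ways from E15 to P3. Of 28 neural stem and radial glial genes, 11 rose, 2 fell, Pax6 (log2 -1.01) and Emx1 (-1.10), and 15 did not pass, against 14 and 5 when adjusted over the list alone. The glutamate transporter gene Slc1a3 rose from 217 ± 23.9 to 1831 ± 582 TPM (log2 3.04), and the endothelin receptor gene Ednrb (3.17) and the receptor phosphatase gene Ptprz1 (3.15) also rose. The median was 0.47 (camera in limma, Benjamini-Hochberg adjusted p = 0.000551, and adjusted p = 0.254 with an estimated correlation). Of 11 genes associated with outer radial glia, 8 rose and none fell, or 10 and none when adjusted over the list alone, with a median of 1.16 (camera in limma, Benjamini-Hochberg adjusted p = 3.62e-10, and adjusted p = 0.196 with an estimated correlation). Acsbg1, which is also on the astrocyte list, rose by 4.06 (SE 0.33), and the outer radial glia list also holds Hopx, on which the cells were sorted. Both counts of risen genes were lower without E15 replicate 1 or 2, and the outer radial glia count also without P3 replicate 1. Each of these fits leaves a stage with 1 library, which by itself makes calls harder to reach. Hopx, on both lists, had a log2 change of 1.179, 1.125 and 0.8506 without E15 replicate 1, E15 replicate 2 and P3 replicate 1, against 1.152 as reported. No radial glial gene fell without E15 replicate 1, E15 replicate 2 or P3 replicate 1, and 1 fell without Adult replicate 2. The radial glial median was 0.18 with the 10 most abundant genes left out. The Emx1 call was also lost without P3 replicate 3 (limma, Benjamini-Hochberg adjusted p = 0.112) and with median-of-ratios scaling (0.0896), and the calls of Pax6 and Emx1 with limma without the trend (0.0828 and 0.0745) and with the replicate block (0.0523 and 0.127). P3 replicate 3 minus replicate 1 had a median of -0.37 for the radial glial list and -0.60 for the outer radial glia list.

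Some genes for transmitter handling, matrix and lipid metabolism also rose from E15 to P3. These lists share members with those above, so their results are not independent. Slc1a2 and Glul are also astrocyte markers, Slc1a3 is on the radial glial list, and Tnc and Itgb5 are on the outer radial glia list. Acaa2, Cpt1a, Thrsp, Scd2, Sparc and Sparcl1 are on the quiescent stem cell list. Of 17 genes for glial transmitter uptake and receptors, 8 rose and none fell, against 10 and 1 when adjusted over the list alone. Among them were the metabotropic glutamate receptor gene Grm3 (log2 3.84), Gabrg1 (3.75) and the glutamate transporter gene Slc1a2 (3.52). The list median was 1.62, and 1.07 with a pseudocount of 5 (for the list, camera in limma, Benjamini-Hochberg adjusted p = 3.41e-09, and adjusted p = 0.193 with an estimated correlation). Of 24 extracellular matrix genes, 12 rose and none fell, against 15 and 2 when adjusted over the list alone. Hapln1 (3.76) and Sdc4 (3.03) were among those that rose (for the list, camera in limma, Benjamini-Hochberg adjusted p = 3.04e-10, and adjusted p = 0.193 with an estimated correlation). Of 17 fatty acid oxidation genes, 6 rose and none fell, or 10 and none when adjusted over the list alone. The acyl-CoA dehydrogenase gene Acadl (2.10) and Acaa2 (1.82) were among them, and the median was 0.54 (camera in limma, Benjamini-Hochberg adjusted p = 1.54e-07, and adjusted p = 0.196 with an estimated correlation). Of 20 genes of lipid and cholesterol synthesis, 6 rose and none fell, against 9 and 1 when adjusted over the list alone. Thrsp rose by 3.40 (for the list, camera in limma, Benjamini-Hochberg adjusted p = 2.99e-05, and adjusted p = 0.196 with an estimated correlation). The matrix count was 5, 4 and 6 and the fatty acid oxidation count was 2, 2 and 2 without E15 replicate 1, E15 replicate 2 and P3 replicate 1. The lipid count was 1 without E15 replicate 2 and 3 without P3 replicate 1. The median difference of P3 replicate 3 minus replicate 1 was -0.23 for the transmitter list, -0.41 for the matrix list, -0.22 for the fatty acid oxidation list and -0.26 for the lipid list.

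None of 25 S phase genes and none of 25 genes of G2 and M phase passed between E15 and P3 (limma), and 3 of each list were lower at an unadjusted p under 0.05. Pcna, the DNA polymerase clamp, was at 368 ± 1.12 TPM at E15 and 418 ± 37.5 TPM at P3, and Cdk1 was at 406 ± 85.1 and 304 ± 49.4 TPM. The list medians were -0.25 and -0.66 (camera in limma, Benjamini-Hochberg adjusted p = 0.182 and 0.00229, and adjusted p = 0.768 and 0.553 with an estimated correlation). Immature neuron genes had a median of -1.46 (camera in limma, Benjamini-Hochberg adjusted p = 2.99e-05, and adjusted p = 0.337 with an estimated correlation). None of the 19 passed over all genes (limma), 13 were lower at an unadjusted p under 0.05, and 11 fell when adjusted over the list alone. With P3 replicate 3 left out, 8 immature neuron genes fell, and none fell without P3 replicate 1. Of 15 intermediate progenitor genes, 1 fell, Gadd45g (log2 -0.73, SE 0.17), against 7 when adjusted over the list alone, with a median of -1.22 (camera in limma, Benjamini-Hochberg adjusted p = 0.000428, and adjusted p = 0.406 with an estimated correlation). The Gadd45g call was lost without E15 replicate 1 or 2, P3 replicate 1 or 3, or Adult replicate 2 (limma, Benjamini-Hochberg adjusted p = 0.198, 0.196, 0.208, 0.0855 and 0.0606), with median-of-ratios scaling (0.0658) and with the replicate block (0.155), and 3 and 2 members fell without P3 replicate 3 and Adult replicate 1. Without P3 replicate 1 the list medians were -0.71 for immature neurons, -0.73 for intermediate progenitors, -0.28 for G2 and M phase and -0.10 for S phase. The median was -0.9987 for G2 and M phase without P3 replicate 3. For S phase it was -0.42 without P3 replicate 3, -0.12 and -0.40 without E15 replicate 1 and 2, -0.10 with median-of-ratios scaling and -0.07 with the replicate block. Between the P3 libraries, the median of replicate 3 minus replicate 1 was 1.21 for immature neuron genes, 0.66 for intermediate progenitor genes, 0.30 for S phase genes and 0.69 for genes of G2 and M phase. Neurod6, a gene of young excitatory neurons, was at 9.88 TPM in P3 replicate 1 and 242 TPM in replicate 3.

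Some markers of other cell types rose at P3 as well. All 9 ependymal markers tested rose, with the same count when adjusted over the list alone and a median of 3.95 (camera in limma, Benjamini-Hochberg adjusted p = 3.74e-13, and adjusted p = 0.117 with an estimated correlation). Dynlrb2, a dynein light chain gene of motile cilia, rose by 4.86 (SE 0.41), and Tmem212 was at 0.237 and 0 TPM at E15 and at 46.7 and 62.0 TPM at P3. Of 16 microglia markers, 5 rose and none fell, or 9 and none when adjusted over the list alone. They included the complement gene C1qb (log2 4.38), Ctss (3.29), Cd68 (1.84) and Tyrobp, which was listed at 0 in both E15 libraries (for the list, camera in limma, Benjamini-Hochberg adjusted p = 6.49e-08, and adjusted p = 0.193 with an estimated correlation). Of 6 mural cell markers 3 rose, or 6 when adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 9.94e-06, and adjusted p = 0.166 with an estimated correlation). These were Higd1b (log2 2.80), Rgs5 (3.08) and Vtn, which was listed at 0 in both E15 libraries and at 4.33 and 6.96 TPM at P3. Olig1 (4.08), Olig2 (2.52) and Ednrb made up the 3 of 5 oligodendrocyte progenitor markers tested that rose, over all genes and adjusted over the list alone. That list held 12 genes, of which only these 5 passed the filter, and Ednrb is also on the radial glial list (for the list, camera in limma, Benjamini-Hochberg adjusted p = 0.000458, and adjusted p = 0.193 with an estimated correlation). Without E15 replicate 1, E15 replicate 2 or P3 replicate 1, 5 ependymal markers rose, and the calls of Rgs5 (limma, Benjamini-Hochberg adjusted p = 0.0508, 0.103 and 0.109) and Olig2 (0.0985, 0.0709 and 0.116, and 0.0655 with the replicate block) were lost. The median of P3 replicate 3 minus replicate 1 was -0.86 for ependymal, -0.32 for microglia, -0.42 for mural and -0.43 for oligodendrocyte progenitor markers. Hemoglobin transcripts were high in 1 E15 library, with Hba-a2 at 1676 TPM in E15 replicate 1 and 3.73 TPM in replicate 2, and none of 5 red blood cell markers passed (limma, 2 lower at an unadjusted p under 0.05). The median of these markers was -3.67, 0.14 without E15 replicate 1, -8.19 without E15 replicate 2 and -1.75 with no filter, and 3 of them fell without E15 replicate 2.

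Across the 15931 genes tested, 885 rose and 172 fell from E15 to P3 (limma, Benjamini-Hochberg), so that 83.7% of the called genes were higher, and 811 and 147 of them changed by at least 2-fold. Beside the glial genes above, the 10 largest increases among the named genes held Ramp1 (5.99), Pla2g3 (5.75), Pla2g7 (5.61), S100a6 (5.53) and Rarres2 (5.39). The largest decrease among the named genes was that of the zinc finger gene Zfp990 (log2 -4.10, SE 0.44, limma, Benjamini-Hochberg adjusted p = 0.00138), and 3 of the other 9 were the histone genes Hist1h2ai, Hist1h2aj and Hist1h3a, members of a family of near-identical copies whose reads are hard to assign. Hist1h3a was at 5.51 and 3.97 TPM at E15 and was listed at 0 in all other libraries. Chga was also among them (-2.33) and lost its call without E15 replicate 1, E15 replicate 2 or P3 replicate 1 (limma, Benjamini-Hochberg adjusted p = 0.148, 0.246 and 0.253), as did Hist1h2ai (0.0600, 0.116 and 0.0669) and Hist1h2aj (0.0660, 0.196 and 0.215, and 0.0908 without P3 replicate 3). With a pseudocount of 0.1 the calls of Chga, Hist1h2ai and Hist1h2aj were lost as well (limma, Benjamini-Hochberg adjusted p = 0.216, 0.0673 and 0.0627). In 9947 genes (62.4%) the libraries of the 2 stages did not overlap, against a chance share of 33.3%. Both counts were lower without E15 replicate 1, E15 replicate 2 or P3 replicate 1. Each of these fits leaves a stage with 1 library, which by itself makes calls harder to reach. Without P3 replicate 3, fewer genes rose and more fell than with all libraries, though this fit also leaves P3 with 1 library. Group size alone therefore does not account for the lower counts without P3 replicate 1. On the first principal component replicate 3 (-44.6) lay nearer to the E15 libraries than replicate 1 (-5.78) did.

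The comparison of the adult with P3 asks how HopX-positive cells differ between early postnatal and adult brain. Gjb6, which encodes the astrocyte gap junction protein connexin 30, rose from 3.18 ± 1.28 (SD, n = 2) to 965 ± 110 TPM (n = 3), a log2 change of 7.88 (SE 0.25, limma, Benjamini-Hochberg adjusted p = 1.20e-05). Of 22 astrocyte markers, 16 rose, none fell and 6 did not pass, with 17 and none when adjusted over the list alone. Itih3 (log2 4.14) and the amino acid transporter gene Slc7a10 (3.56) were among those that rose, while Gfap was at 261 ± 141 TPM at P3 and 107 ± 3.03 TPM in the adult and did not pass (log2 -1.17, SE 0.56, limma, Benjamini-Hochberg adjusted p = 0.172). The list median was 1.89 (camera in limma, Benjamini-Hochberg adjusted p = 4.32e-14, and adjusted p = 0.348 with an estimated correlation). Of 24 quiescent stem cell genes, 16 rose and 1 fell, Id3 (log2 -1.73), over all genes and when adjusted over the list alone, and 2 fell without P3 replicate 3. The metallothionein gene Mt1 rose by 3.62, the chaperone gene Clu by 2.90 and Ntsr2 by 4.22, and the median was 1.72 (camera in limma, Benjamini-Hochberg adjusted p = 1.40e-10, and adjusted p = 0.380 with an estimated correlation). Of 17 genes for glial transmitter uptake and receptors, 11 rose and 2 fell, or 12 and 2 when adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 1.90e-06, and adjusted p = 0.348 with an estimated correlation). Slc1a2 rose (2.52), and the receptor genes Grm5 (-1.73) and P2ry1 (-1.39) fell. Without P3 replicate 3, 6 members of the transmitter list rose and 1 fell, and 1 fell without P3 replicate 1 or any 1 of the adult libraries.

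Genes of dividing cells fell from P3 to the adult. Of 25 genes of G2 and M phase, 24 fell and none rose, or 25 and none when adjusted over the list alone, with a median of -2.88 (camera in limma, Benjamini-Hochberg adjusted p = 3.50e-14, and adjusted p = 0.348 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, fell from 38.5 ± 14.4 to 0.604 ± 0.202 TPM (log2 -4.58, SE 0.35), and Aurka (-4.09), Ube2c (-3.63) and Ccnb2 (-3.62) fell with it. Of 25 S phase genes, 19 fell and none rose, or 21 and none when adjusted over the list alone, with a median of -1.68 (camera in limma, Benjamini-Hochberg adjusted p = 5.81e-09, and adjusted p = 0.348 with an estimated correlation). Mcm2 fell by 2.42 on the log2 scale, a call that was lost without P3 replicate 1 or 3 (limma, Benjamini-Hochberg adjusted p = 0.0541 and 0.101), and its log2 change was -1.50 with Adult replicates 1 and 3 left out together. Without P3 replicate 3, 12 genes of G2 and M phase and 4 S phase genes fell, and without P3 replicate 1, 10 S phase genes fell. The median of replicate 3 minus replicate 1 at P3 was 0.69 for the G2 and M list and 0.30 for the S phase list, and the medians of Adult replicates 1 and 3 minus replicate 2 were -0.82 and -0.38 for G2 and M and -0.94 and -0.59 for S phase.

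Of 28 neural stem and radial glial genes, 5 rose, 8 fell and 15 did not pass from P3 to the adult. The 5 were Ttyh1, Pla2g7, Slc1a3, Prom1 and Hopx, and the counts stood against 9 and 9 when adjusted over the list alone. The brain fatty acid binding protein gene Fabp7 fell from 17690 ± 5650 to 2004 ± 265 TPM (log2 -3.11), the matrix gene Tnc fell (-2.50) and the membrane protein gene Ttyh1 rose (1.96). The list median was -0.07, and it was 0.08 with median-of-ratios scaling, 0.02 with the 10 most abundant genes left out, 0.01 without P3 replicate 1, -0.01 with quantile normalization and -0.02 with Adult replicates 1 and 3 left out together (for the list, camera in limma, Benjamini-Hochberg adjusted p = 0.853, and adjusted p = 0.924 with an estimated correlation). With P3 replicate 3 left out, 3 members rose and 4 fell. Some genes of neuronal production fell. Of 15 intermediate progenitor genes, 11 fell and none rose, or 13 and none when adjusted over the list alone. The transcription factor gene Eomes fell by 3.01 on the log2 scale and Neurod4 by 2.77 (for the list, camera in limma, Benjamini-Hochberg adjusted p = 1.90e-06, and adjusted p = 0.348 with an estimated correlation). Of 19 immature neuron genes, 9 fell and none rose, or 11 and none when adjusted over the list alone. Dpysl3 (-3.38) and Sox11 (-2.95) were among them (for the list, camera in limma, Benjamini-Hochberg adjusted p = 3.35e-05, and adjusted p = 0.380 with an estimated correlation). Without P3 replicate 3, 7 intermediate progenitor genes and 5 immature neuron genes fell. The P3 libraries differed in both lists, with medians of replicate 3 minus replicate 1 of 0.66 and 1.21.

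All 39 cytosolic ribosomal protein genes fell from P3 to the adult, with the same count when adjusted over the list alone and 37 with median-of-ratios scaling. The list median was -1.15, and Rpl13 fell by 1.71 and Rplp0 by 1.70 (for the list, camera in limma, Benjamini-Hochberg adjusted p = 1.15e-22, and adjusted p = 0.348 with an estimated correlation). Of 13 mitochondrially encoded genes, 12 rose and 1 fell over all genes and when adjusted over the list alone. Here mt-Nd2 (log2 1.88) and mt-Cytb (1.59) rose while mt-Atp8 fell (-3.04) (for the list, camera in limma, Benjamini-Hochberg adjusted p = 2.85e-10, and adjusted p = 0.348 with an estimated correlation). The mt-Atp8 call was lost without E15 replicate 1 or 2, P3 replicate 1 or 3, or Adult replicate 1 or 2 (limma, Benjamini-Hochberg adjusted p = 0.109, 0.109, 0.219, 0.203, 0.0985 and 0.0963). No mitochondrially encoded gene fell with median-of-ratios scaling, quantile normalization or the 10 most abundant genes left out. Of 15 immediate early genes, 5 fell and none rose, or 10 and none when adjusted over the list alone. These were Egr1 (-2.68), Fos (-2.49), Ier2 (-2.02), Btg2 (-2.02) and Fosb (-1.71), and 8 fell without Adult replicate 1 (for the list, camera in limma, Benjamini-Hochberg adjusted p = 0.000382, and adjusted p = 0.348 with an estimated correlation). Of 24 extracellular matrix genes, 8 rose and 6 fell, or 8 and 7 when adjusted over the list alone, with Sdc4 rising by 2.97 and the proteoglycan gene Ncan at a log2 change of -3.37 (for the list, camera in limma, Benjamini-Hochberg adjusted p = 0.547, and adjusted p = 0.811 with an estimated correlation). The matrix median of -0.04 was 0.08 with median-of-ratios scaling, 0.04 with quantile normalization, 0.04 with the 10 most abundant genes left out, 0.04 without P3 replicate 1, 0.16 without Adult replicate 1, 0.08 with Adult replicates 1 and 3 left out together and 0.425 with a mean of at least 5 TPM. It was -0.24 without Adult replicate 2, the lowest over the alternatives, and 4 matrix genes rose without P3 replicate 3.

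Several other cell type lists moved between P3 and the adult. Of 9 ependymal markers, 8 fell and 1 rose, Rarres2 (log2 1.65), over all genes and when adjusted over the list alone, and Rarres2 did not pass without P3 replicate 3. Pifo was at 43.5 and 38.2 TPM at P3 and at 0, 0.323 and 0.179 TPM in the adult (log2 -5.17, SE 0.39). Tmem212 was at 0, 0 and 0.2496 TPM in the adult (for the list, camera in limma, Benjamini-Hochberg adjusted p = 3.35e-05, and adjusted p = 0.348 with an estimated correlation). Of 6 mural cell markers, 5 fell, and 5 fell and 1 rose when adjusted over the list alone. Rgs5 fell by 2.71 on the log2 scale, and 3 fell without P3 replicate 1 (for the list, camera in limma, Benjamini-Hochberg adjusted p = 0.0119, and adjusted p = 0.348 with an estimated correlation). Of 16 microglia markers, 9 rose and none fell, or 13 and none when adjusted over the list alone. They included Ctss (3.61) and Siglech (3.34), and 4 rose without P3 replicate 3 (for the list, camera in limma, Benjamini-Hochberg adjusted p = 6.93e-09, and adjusted p = 0.348 with an estimated correlation). Of 20 genes of class I antigen presentation and the interferon response, 6 rose and none fell, or 9 and none when adjusted over the list alone. They included B2m (1.67), and 3 rose without P3 replicate 3 (for the list, camera in limma, Benjamini-Hochberg adjusted p = 3.78e-06, and adjusted p = 0.348 with an estimated correlation). Of 15 mature oligodendrocyte markers 1 rose, Cryab (1.95), with the same count when adjusted over the list alone and a median of 1.64 (camera in limma, Benjamini-Hochberg adjusted p = 0.00151, and adjusted p = 0.560 with an estimated correlation). The adult libraries differed in this list, with Mog, a myelin glycoprotein gene, at 26.4, 0 and 31.5 TPM in replicates 1, 2 and 3. Without Adult replicate 2, 9 oligodendrocyte markers rose, the median was 0.73, 1.01 and 1 without Adult replicate 1, Adult replicate 3 and P3 replicate 3, and with Adult replicates 1 and 3 left out together the median was -0.14. Of 18 mature neuron genes 7 rose and none fell, with the same counts when adjusted over the list alone, and the calcium sensor gene Vsnl1 rose by 2.77 (for the list, camera in limma, Benjamini-Hochberg adjusted p = 0.000588, and adjusted p = 0.522 with an estimated correlation). The mature neuron count was 1 without P3 replicate 3, 2 (with 1 fallen) without P3 replicate 1, 3 without E15 replicate 1 or 2 and 4 without Adult replicate 1 or 3, and the list medians of Adult replicates 1 and 3 minus replicate 2 were 1.24 and 0.94.

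The Y-linked genes Ddx3y (log2 3.67) and Eif2s3y (3.60) rose from P3 to the adult with Uty (2.22) and Kdm5d (1.76), which made all 4 sex-linked genes tested, with the same count when adjusted over the list alone. The P3 libraries were the lowest of the 3 stages for these genes. Levels of Y-linked genes also depend on the share of male cells, and sex is not among the sample details used here. Xist and Tsix, also on the list, had no row among the deposited values. A difference in sex between the libraries therefore cannot be told apart from a change with stage. None of the 4 passed from E15 to P3 (limma, 4 lower at an unadjusted p under 0.05), 4 fell when adjusted over the list alone, and the median was -1.48, and -0.91 without P3 replicate 1. With P3 replicate 3 left out, 2 fell over all genes. Ddx3y was at 6.26 and 7.43 TPM at E15, 0.544 and 3.58 TPM in P3 replicates 1 and 3, and 30.9, 35.7 and 31.9 TPM in the adult. All 4 were higher in P3 replicate 3 than in replicate 1, by a median of 1.28. From E15 to the adult 2 rose, Ddx3y (2.11) and Eif2s3y (2.18), with the same count when adjusted over the list alone, and none rose without E15 replicate 1 or 2. Kdm5d lost its call from P3 to the adult without P3 replicate 1 or 3 (limma, Benjamini-Hochberg adjusted p = 0.133 and 0.0980) or with no filter (0.0608), and 1 of the 4 rose from P3 with Adult replicates 1 and 3 left out together, when from E15 none did. Across all genes, 1337 rose and 2193 fell (limma, Benjamini-Hochberg), and 1120 and 1671 of them changed by at least 2-fold. Of the called genes 37.9% were higher, against 49.4% with median-of-ratios scaling (1699 higher and 1744 lower) and 48.1% with quantile normalization. Other named genes among the largest increases were Etnppl (7.18), Hsd11b1 (5.81), Sult1a1 (5.70), Atp13a4 (5.23), Fam107a (4.98) and Fbln5 (4.82), and Pygm (5.04) is uncertain because it shares its values with another gene entry of the table. The largest decreases of named genes included Tm4sf1 (-5.72), Fam216b (-4.82) and Plac9b (-4.55), and Grb10, an imprinted adaptor gene, was at 18.7 and 50.5 TPM at P3 and was listed at 0 in all 3 adult libraries. The libraries did not overlap in 7820 genes (49.1%), against a chance share of 20%. Without P3 replicate 1 the counts were 881 and 1383, and without P3 replicate 3 they were 436 and 671.

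**Figure D2:**
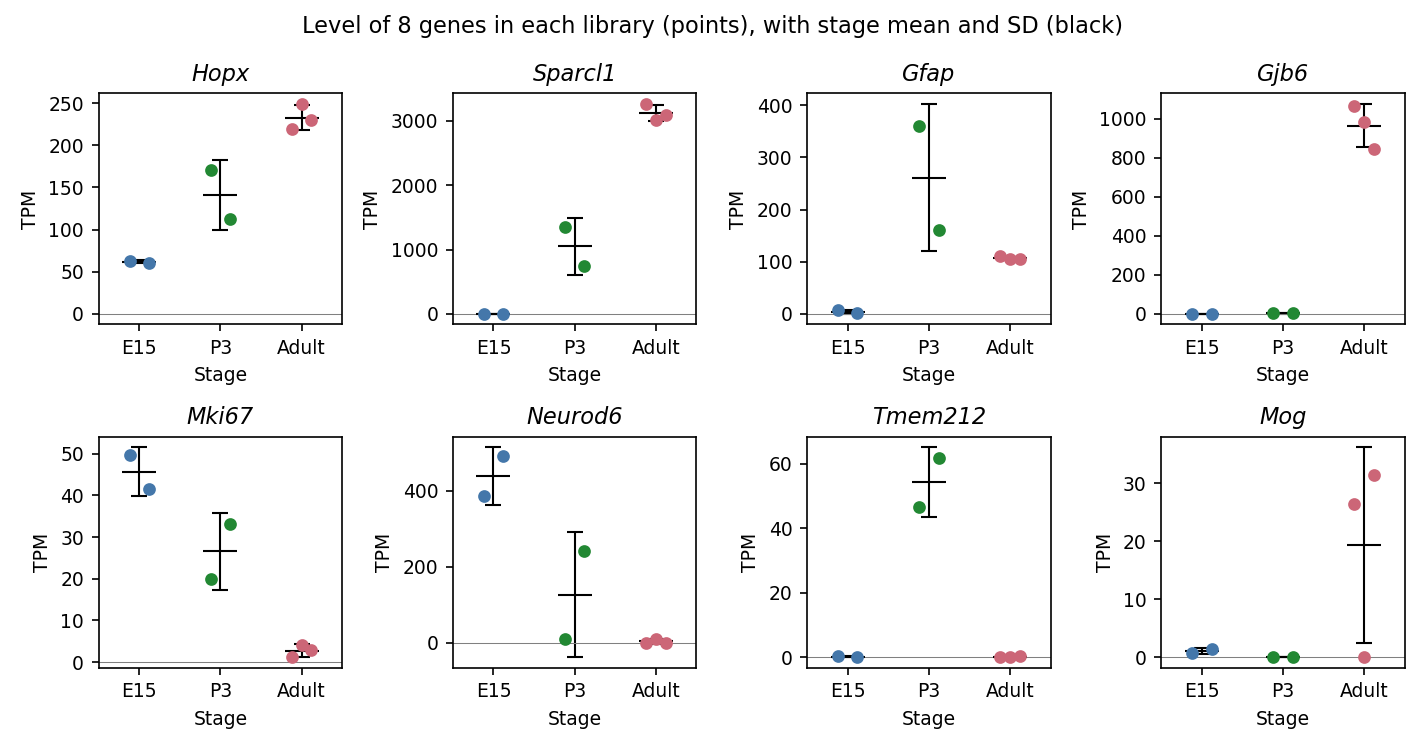
TPM of 8 genes in each library at E15, P3 and in the adult, with 1 point per library and the mean and SD of each stage. Gjb6 was at 965 ± 110 TPM in the adult (n = 3) and 3.18 ± 1.28 TPM at P3 (n = 2), Tmem212 was high only in the P3 libraries (46.7 and 62.0 TPM), and Mog spread from 0 to 31.5 TPM among the adult libraries.

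The comparison of the adult with E15 spans the full interval. Glial genes were among the largest increases. Gjb6 rose by a log2 change of 9.49 (SE 0.25, limma, Benjamini-Hochberg adjusted p = 1.58e-06), Sparcl1 by 9.33 (SE 0.28, adjusted p = 1.58e-06) and Hsd11b1, a glucocorticoid-activating enzyme gene, by 9.32 (SE 0.26, adjusted p = 1.58e-06). All 22 astrocyte markers rose, with the same count when adjusted over the list alone and a median of 5.23 (camera in limma, Benjamini-Hochberg adjusted p = 6.26e-24, and adjusted p = 0.309 with an estimated correlation). Of 24 quiescent stem cell genes, 23 rose and none fell, with the same counts when adjusted over the list alone and a median of 4.10 (camera in limma, Benjamini-Hochberg adjusted p = 1.39e-21, and adjusted p = 0.309 with an estimated correlation). Apoe rose from 90.1 ± 13.4 (n = 2) to 7204 ± 675 TPM (n = 3), and Mt1 from 369 ± 61.9 to 27790 ± 3441 TPM. Of 28 neural stem and radial glial genes, 14 rose and 9 fell over all genes and when adjusted over the list alone. Slc1a3 rose by 4.36 and the intermediate filament gene Nes fell by 3.43 on the log2 scale (for the list, camera in limma, Benjamini-Hochberg adjusted p = 0.059, and adjusted p = 0.434 with an estimated correlation). Of 11 genes associated with outer radial glia, 8 rose and 2 fell over all genes and when adjusted over the list alone. Fam107a (7.02) and Acsbg1 (5.69) rose (for the list, camera in limma, Benjamini-Hochberg adjusted p = 0.000122, and adjusted p = 0.368 with an estimated correlation). The 2 that fell were Tnc (-0.86) and Pea15a (-0.85), of which none passed without E15 replicate 1 or with median-of-ratios scaling, and 1 passed without E15 replicate 2, Adult replicate 1 or Adult replicate 3.

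Most genes of the lists for immature neurons, intermediate progenitors and division were lower in the adult than at E15. Dct was at 140 and 117 TPM at E15 and at 0, 0.834 and 0 TPM in the adult (log2 -6.72, SE 0.74, limma, Benjamini-Hochberg adjusted p = 0.000281), and the netrin receptor gene Dcc (-5.45), Plppr1 (-5.86) and Fam110a (-5.65) fell as well. Neurod6 (-7.20) and Mpped1 (-5.40) fell, and lost their calls without E15 replicate 2 (limma, Benjamini-Hochberg adjusted p = 0.0505 and 0.0529). Of 19 immature neuron genes, 17 fell and 1 rose, Ncam1 (0.76), or 18 and 1 when adjusted over the list alone, with a median of -3.34 (camera in limma, Benjamini-Hochberg adjusted p = 1.82e-06, and adjusted p = 0.347 with an estimated correlation). Of 15 intermediate progenitor genes, 13 fell and none rose, or 14 and none when adjusted over the list alone, including Eomes (-4.23) (for the list, camera in limma, Benjamini-Hochberg adjusted p = 6.68e-07, and adjusted p = 0.347 with an estimated correlation). All 25 genes of G2 and M phase fell, with the same count when adjusted over the list alone and a median of -3.37 (camera in limma, Benjamini-Hochberg adjusted p = 2.22e-11, and adjusted p = 0.317 with an estimated correlation). Of the S phase genes, 23 of 25 fell, or 24 when adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 2.39e-07, and adjusted p = 0.365 with an estimated correlation). Without E15 replicate 1 and 2, 11 and 9 immature neuron genes and 11 and 14 S phase genes fell, and the 1 immature neuron gene did not rise without either of them, either P3 library, or Adult replicate 1 or 2. All 39 ribosomal protein genes fell, with the same count when adjusted over the list alone and a median of -1.52 (camera in limma, Benjamini-Hochberg adjusted p = 2.66e-19, and adjusted p = 0.309 with an estimated correlation). Of 24 chromatin regulators, 16 fell and none rose, with the same counts when adjusted over the list alone. Smarca4 (-2.98) and Ezh2 (-2.02) were among them, and 8 and 6 fell without E15 replicate 1 and 2 (for the list, camera in limma, Benjamini-Hochberg adjusted p = 0.0003, and adjusted p = 0.418 with an estimated correlation). The brain region taken at each stage, on which genes of regional identity also depend, is not given in the labels. Of 12 genes of dorsal telencephalic identity, 8 fell and 1 rose, Prox1 (0.87), over all genes and when adjusted over the list alone. Those that fell included Emx1 (-2.22) and Pax6 (-1.60) (for the list, camera in limma, Benjamini-Hochberg adjusted p = 0.0062, and adjusted p = 0.309 with an estimated correlation). For this list 5 fell and none rose without E15 replicate 1 or 2, and none rose without Adult replicate 1 or 3. The Prox1 call was also lost with the replicate block (limma, Benjamini-Hochberg adjusted p = 0.0793) and with Adult replicates 1 and 3 left out together (0.248, log2 0.57).

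Some markers of immune cells and oligodendrocytes were higher in the adult than at E15. Of 16 microglia markers, 14 rose and none fell, or 15 and none when adjusted over the list alone. Ctss rose by 6.90 and C1qb by 6.15 (for the list, camera in limma, Benjamini-Hochberg adjusted p = 5.08e-11, and adjusted p = 0.309 with an estimated correlation). The microglial adaptor gene Tyrobp was listed at 0 in both E15 libraries and was at 32.6, 77.2 and 74.4 TPM in the adult. Of 20 genes of class I antigen presentation and the interferon response, 13 rose and none fell, or 14 and none when adjusted over the list alone. They included Ifi27 (6.61) and H2-K1 (3.50), and 8 and 7 rose without E15 replicate 1 and 2, while 1 fell without Adult replicate 3 (for the list, camera in limma, Benjamini-Hochberg adjusted p = 4.29e-07, and adjusted p = 0.309 with an estimated correlation). Of 15 mature oligodendrocyte markers, 7 rose and none fell over all genes and when adjusted over the list alone, with a median of 2.51, and 1.55 with a pseudocount of 5 (for the list, camera in limma, Benjamini-Hochberg adjusted p = 9.41e-05, and adjusted p = 0.428 with an estimated correlation). The count was 3 without E15 replicate 1 or 2 and 13 without Adult replicate 2, in which Mog was listed at 0 against 26.4 and 31.5 TPM in the other adult libraries, and the median was -0.05 with Adult replicates 1 and 3 left out together. Of 9 ependymal markers, 2 rose, Rarres2 (7.04) and Dynlrb2 (1.74), and 1 fell, Pifo (-1.42), over all genes and when adjusted over the list alone. The median of -0.03 was 0.09 with median-of-ratios scaling or quantile normalization, 0.17 with the replicate block, 0.15 without E15 replicate 2, 0.01 without Adult replicate 2, 0.06 without Adult replicate 3 and -0.08 without Adult replicate 1 (for the list, camera in limma, Benjamini-Hochberg adjusted p = 0.272, and adjusted p = 0.493 with an estimated correlation). Without E15 replicate 1, 1 ependymal marker rose and none fell. The Pifo call was lost with a pseudocount of 5, quantile normalization and the replicate block (limma, Benjamini-Hochberg adjusted p = 0.0983, 0.0556 and 0.0565). The endothelial gene Pecam1 was at 137 ± 69.4 TPM at E15, 112 ± 33.9 TPM at P3 and 121 ± 35.7 TPM in the adult, and 1 of 8 endothelial markers fell, Kdr (log2 -1.26), with no call when adjusted over the list alone (limma, 1 lower at an unadjusted p under 0.05). The Kdr call was lost without E15 replicate 1 or 2 (limma, Benjamini-Hochberg adjusted p = 0.101 and 0.0525), with quantile normalization (0.0606) and with the replicate block (0.0746), and 2 endothelial markers rose without Adult replicate 3.

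Across all genes, 2457 rose and 3930 fell from E15 to the adult (limma, Benjamini-Hochberg), and 2115 and 3244 of them changed by at least 2-fold. Of the called genes 38.5% were higher, against 52.5% with median-of-ratios scaling (3063 higher and 2775 lower), 46.7% with quantile normalization and 45.8% with the 10 most abundant genes left out. The median log2 change of all tested genes was -0.15 from E15 to P3, -0.13 from P3 to the adult and -0.30 from E15 to the adult, and -0.03, -0.01 and -0.06 with median-of-ratios scaling. The largest increases of named genes also held Gpr37l1 (8.55), Cldn10 (8.13) and the tissue factor gene F3 (7.56). Hist1h2ab was at 56.8 and 59.2 TPM at E15 and was listed at 0 in the adult. The libraries did not overlap in 9734 genes (61.1%), against a chance share of 20%. Without E15 replicate 1 the counts were 1593 and 1865, and without E15 replicate 2 they were 1540 and 1856.

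**Figure D3:**
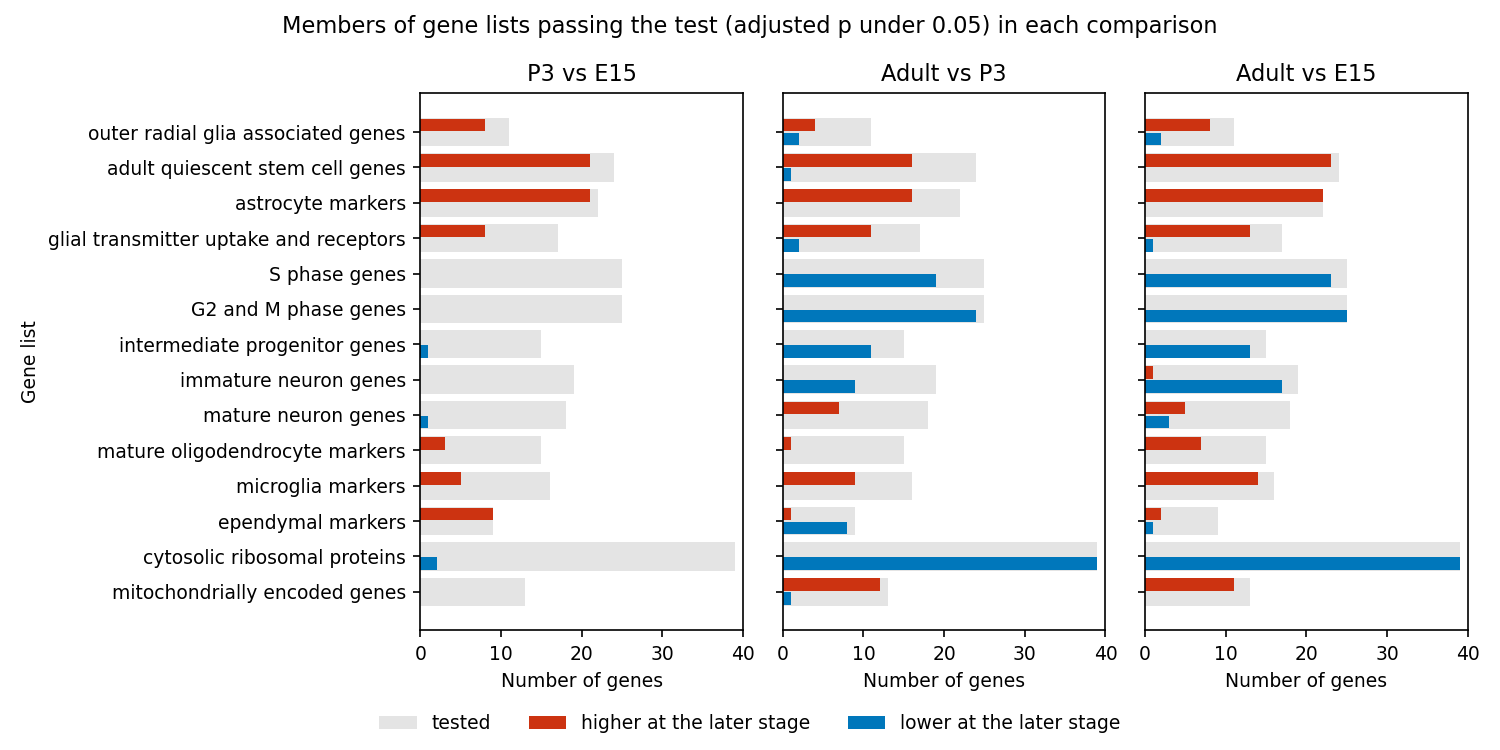
Number of genes tested, higher and lower (limma, adjusted p under 0.05 over all genes) in 14 of the gene lists, for each of the 3 comparisons. All 39 ribosomal protein genes were lower in the adult than at P3, and 21 of 22 astrocyte markers were higher at P3 than at E15.

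Over the 3 stages, 5962 genes (37.4%) changed in the moderated F test (limma, Benjamini-Hochberg), a count that was 3342 and 3205 without E15 replicate 1 and 2. For 1247 genes (7.83%), the 95% confidence intervals of all 3 pairwise differences lay within 1 on the log2 scale, including 1163 of the 8049 genes with a mean of at least 10 TPM. That count of 1247 was lower with any 1 library of E15 or P3 left out. It was 6048 with a pseudocount of 5 and 7610 with no filter, which adds genes near 0. Genes such as Slc1a2 (log2 3.52, then 2.52) and Ntsr2 (4.31, then 4.22) rose in both steps and belong to a set of 319 genes, against 74.3 for independent lists. Egr1 (3.48, then -2.68) and Tmem212 (5.62, then -5.67) rose and then fell with 163 genes, against 122 for independent lists. Zfp990 fell and then rose (-4.10, then 3.55) with 33 genes, against 14.4, and 19 genes fell in both steps, against 23.7. Simulations with no effect gave 0 genes in each of these sets, but they left 15930 of 15931 genes uncalled in both steps on average, so they set no chance level for these counts. Across genes, which are not independent replicates, the changes of the first and second step had a correlation of 0.11, against -0.55 with no effect, and a covariance of 0.10, against -0.11. Both steps share the P3 libraries, which are too few to split, so part of the differences from independent lists may come from the shared libraries for the sets that changed direction and for the set that fell in both steps. The negative covariance with no effect works against genes that rose in both steps.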

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

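Leaving out Adult replicates 1 and 3 together, leaving out the 10 most abundant genes and testing identical genes once were chosen after the results were seen. Depth is unknown for these values, so its limit cannot be given, though the adult libraries had a larger share of genes at 0. Named genes kept their side of the threshold in 8252 of 9056 combinations of result and alternative (793 weaker, 11 stronger). Of the lost calls of named genes, 25 to 97 were lost with each library left out, 105 with Adult replicates 1 and 3 left out together, 63 in fits on the 2 compared stages alone, 51 with no filter, 50 with the replicate block and 36 with limma without the trend. None that passed as reported changed sign, and those that did not pass changed sign in 24 combinations. Genes picked because their stages did not overlap cannot change sign with 1 library left out, so the first result was partly set by the choice. The gene lists had 115 weaker and 18 stronger calls (camera in limma) in 2673 combinations. The median of a list changed sign or became 0 in 91 combinations for lists with no call as reported and in 4 for lists with one. These 4 were mature oligodendrocyte markers from P3 to the adult (median -0.1396) and from E15 to the adult (-0.05136) with Adult replicates 1 and 3 left out together, which removes the adult libraries with high values, the same markers from E15 to P3 with the replicate block (-0.6599), and mature neuron genes from E15 to the adult with a mean of at least 5 TPM (-0.1641). The direction of camera changed in the first of them and in 35 combinations for lists with no call. With an estimated correlation no list call held, and the smallest adjusted p (camera in limma, Benjamini-Hochberg) was 0.117, for ependymal markers from E15 to P3. Of the 180 combinations for counts of genes, 145 stayed within 1.5 times the reported count. With 1 library left out, genes higher and lower numbered 204 to 818 and 14 to 319 from E15 to P3, 436 to 1311 and 671 to 2084 from P3 to the adult, and 1540 to 2436 and 1856 to 3775 from E15 to the adult. Genes changed among the stages then numbered 3205 to 5498, and genes with a shared level 632 to 1210. From E15 to P3, 98 genes were lower with a pseudocount of 0.1 and 546 with array weights, and fits on the libraries of E15 and P3 alone gave 387 higher and 52 lower. Genes with a shared level numbered 6048 with a pseudocount of 5 and 7610 with no filter, which adds genes near 0. Without Adult replicates 1 and 3, 402 genes were higher and 53 lower from E15 to P3, 569 higher and 1129 lower from P3 to the adult, and 3590 changed among the stages. Leaving out 1 library of E15 or P3 leaves that stage with 1 library, which by itself makes calls harder to reach. Hopx kept its log2 change of 0.7448 from P3 to the adult without either E15 library, yet lost its call. More genes fell from E15 to P3 without P3 replicate 3 than with all libraries, so group size alone does not set these counts. Other than for the filter and the oligodendrocyte markers, further causes of the differences in counts were not tested. With the replicate number as a replicate block, 556 genes were higher and 60 lower from E15 to P3 and 753 had a shared level. Between same-numbered samples, the correlations of their deviations from the stage means across genes ranged from -0.0232 to 0.0207. These values cannot exclude a shared batch, whose effect need not be the same at each stage. The labels do not say that equal numbers share an animal, litter or day. A count-based test was not run because the values are TPM.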

Other observations

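The families in this and the next paragraph, the tests of the P3 replicates against postmitotic neurons and against library scaling, and both tests of the oligodendrocyte genes were chosen after the results were seen, and the oligodendrocyte tests were revised from a first form with the same outcome. The remaining tests were written before their results. Other families picked by symbol, such as Zfp, Slc and kinesin genes, were tested too and are not reported here. Within a comparison, camera p-values were adjusted over all families with at least 5 tested members. Replication-dependent histone genes are transcribed mainly in S phase. Of 58 tested histone cluster genes, which are near-identical copies and so uncertain, none rose and 6 fell from E15 to P3, 6 rose and 17 fell from P3 to the adult, and 5 rose and 36 fell from E15 to the adult. The medians were -0.91, -1.06 and -1.83, and they were -0.79, -1.004 and -1.67 with median-of-ratios scaling (camera in limma, Benjamini-Hochberg adjusted p = 2.21e-05, 0.0154 and 0.000118, and adjusted p = 0.0491, 0.159 and 0.066 with an estimated correlation). Hist1h2ap was at 1560 and 1495 TPM at E15, 659 and 721 TPM at P3, and 40.8, 151 and 80.1 TPM in the adult (log2 -4.25 from E15, SE 0.43, limma, Benjamini-Hochberg adjusted p = 0.00019). Hist1h2bc went the other way, from 64.6 and 71.9 TPM at E15 to 294, 363 and 272 TPM in the adult (log2 2.16, SE 0.18). From E15 to P3, 2, 1, 2 and 9 histone genes fell without E15 replicate 1, E15 replicate 2, P3 replicate 1 and P3 replicate 3. From P3 to the adult 9 fell without P3 replicate 3, with a median of -0.50, and 24 and 23 fell from E15 to the adult without E15 replicate 1 and 2.

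Some genes of detoxification and metal binding rose with stage. Of 19 glutathione S-transferase genes, whose products conjugate glutathione to reactive compounds, 6 rose from E15 to P3, 9 rose and 1 fell from P3 to the adult, and 13 rose and 1 fell from E15 to the adult (camera in limma, Benjamini-Hochberg adjusted p = 8.75e-06, 0.000106 and 5.19e-07, and adjusted p = 0.112, 0.159 and 0.0805 with an estimated correlation). Gstm1 was at 54.4 and 71.5 TPM at E15, 1435 and 851 TPM at P3, and 5644, 5821 and 6177 TPM in the adult (log2 6.54 from E15, SE 0.21, limma, Benjamini-Hochberg adjusted p = 1.58e-06), and Gstm5 rose by 3.61 (SE 0.12). The count was 3, 2 and 4 from E15 to P3 without E15 replicate 1, E15 replicate 2 and P3 replicate 1. It was 4 from P3 to the adult without P3 replicate 3, and 8 from E15 to the adult without either E15 library. The metallothionein genes Mt1, Mt2 and Mt3, which are also on the quiescent stem cell list, rose in each comparison. Mt3 was at 182 and 176 TPM at E15 and at 4563, 5024 and 4864 TPM in the adult (log2 4.74, SE 0.20). From E15 to P3, 2 and 1 metallothionein genes rose without E15 replicate 1 and 2.

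Neuronal genes were higher in P3 replicate 3 than in replicate 1, with a median difference of 1.21 for immature neuron genes on the log2 scale. A larger share of postmitotic neurons alone would leave genes of dividing cells level or lower, but genes of G2 and M phase were also higher, by a median of 0.6858 with 25 of 25 above 0. The larger share of neurons is therefore argued against as the whole cause. The size factors of median-of-ratios scaling were 1.027 and 1.071 in P3 replicates 1 and 3. Scaling by 1 such factor per library is too small to give the neuronal difference, so its test could hardly come out otherwise. With this scaling the lower quartile of the immature neuron list stayed at 0.7452. A blend of E15-like and P3-like RNA would place replicate 3 the same share of the way from replicate 1 to E15 in genes higher and in genes lower at E15 than in the adult. The median shares, 0.463 (n = 572) and 0.484 (n = 515), differed by 0.02049. Over genes, the interquartile ranges were 0.341 to 0.604 and 0.406 to 0.586. TPM sum to a nearly fixed total, so gains and losses balance, which draws both medians together whatever separates the replicates. Their closeness therefore cannot tell a blend from other causes. As a hypothesis, P3 replicate 3 may hold more RNA like that of E15 than replicate 1 does. The labels give no group that separates these libraries, so no other biological explanation was tested.

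Mature oligodendrocyte markers were high in Adult replicates 1 and 3 and low in replicate 2, as Mog at 26.4, 31.5 and 0 TPM shows. Library scaling by 1 factor per library is too small a cause, since the size factors of replicates 1, 2 and 3 were 1.003, 0.9507 and 0.8798. The test of it could hardly come out otherwise. With median-of-ratios scaling the median log2 difference to replicate 2 was still at least 3.251 in replicates 1 and 3. Oligodendrocyte RNA in replicates 1 and 3 would also raise a further list of oligodendrocyte genes, of which 20 were tested, and their medians above replicate 2 were 0.5436 in replicate 1 and 0.3978 in replicate 3 against a bound of 0.5. Both medians lay above nearly all random lists matched on mean level (percentiles 99.9 and 99.91), which the explanation also needs. This list holds Ptgds, whose values had been seen, so this explanation cannot be told apart from others, because the percentiles go with it while the sizes lie on both sides of the bound. No biological explanation other than oligodendrocyte RNA was tested, since all 3 libraries belong to the same group.

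Ependymal markers were higher at P3 than at E15 and in the adult, with medians of 3.95 and -3.60 for the changes into and out of P3, the latter -2.33 with a pseudocount of 5. Library scaling by 1 factor per library is too small a cause, since the size factors ranged only from 0.8798 to 1.189. The test of it could hardly come out otherwise. At least 8 of the 9 markers passed in each step with median-of-ratios scaling. Cells with motile cilia in the P3 libraries would also raise a further list of motile cilium genes. Of 46 listed, 34 passed the filter, and these were higher at P3 by a median of 1.268 against E15 and 1.361 against the adult. Some, such as Deup1 and Zmynd10, passed the filter only through the P3 libraries. The filter therefore favours genes high at P3, and part of these medians may come from it. As a hypothesis, the P3 gate may have taken ependymal cells or their precursors, and stage itself stays open as an untested biological explanation. Of the further genes, 8 rose from E15 to P3 and 15 fell from P3 to the adult, including Cfap52 (log2 3.25 and -3.45).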
